A study of Mus musculus with 16 samples.

How the data were processed

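ChIP-seq peak lists of H3K4me3, H3K27ac and H3K27me3 from mESCs were used, 2 Mettl14 control and 2 Mettl14 knockout libraries per mark. Samples were grouped by the mark, genotype and replicate number in their titles, where the knockout is written CKO. The series design also names a Mettl3 knockout, and such samples were not analysed here. The 4 input libraries were not analysed here.

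Per the labels' protocols, cells were fixed with formaldehyde, chromatin was precipitated with a histone ChIP kit with spike-in chromatin and a spike-in antibody, and libraries were made with a KAPA HyperPlus kit. Per the labels, the H3K27ac libraries carry the name of the H3K4me3 antibody. The mark in the title was used. Peak positions and widths set these lists apart from those of H3K4me3, as given below, but the antibody itself could not be checked. Per the submitters' processing notes, CASAVA, Trimmomatic 0.38, Bowtie2 2.4.1, SAMtools and HOMER were used with genome build mm10. Which tool called the peaks, its settings, the use of the inputs and the use of the spike-in reads are not given in the sources used here. A longer list can come from more modified chromatin, deeper sequencing, a better precipitation or another threshold.

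The deposited lists are BED tables with 1 list per library, so the replicates were called separately. Their deposited score column holds the constant 1 for every peak, so it ranks nothing and was not used as a measurement. The strand column is constant too, and each peak is at least 501 bp wide. Peaks of that minimum width made up on average 65.1% of control and 30.7% of knockout lists for H3K4me3. The shares were 51.6% and 46.2% for H3K27ac, and 62.6% and 55.6% for H3K27me3. Peak positions and widths are the only measurements in the lists. They hold no heights, read numbers or p-values. Peaks were ranked by width where a rank was needed.

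Gene positions came from a RefSeq gene table of assembly GRCm38, the assembly of mm10, with gene spans and no strand, exons or UTRs. The design fixed before the data were examined set a window of 1 kb either side of the transcription start. Since the table gives no strand, the window was placed at both ends of each gene, a departure from that design. A peak at a gene end is thus at a start or an end of transcription. No peak lay more than 1 Mb past the last gene of its chromosome, and the 12 lists held 117176 peaks, of which 10 lay on unplaced contigs and could touch no gene-end window. The gene counts of lists take members of any gene type, and the tests protein-coding ones alone. The random level at gene ends came from 100 placements of each list on the same chromosomes.

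An overlap needed at least 1 bp. Per mark, the peaks of the 4 lists were merged into regions. Regions and genes were counted as knockout-only (both knockout lists, neither control list) or control-only, and set against the 4 pairs of 1 control and 1 knockout list, which come from the 2 crossed splits of the lists. These pairs do not correct for unequal list lengths. Peak number and covered length were compared on the log2 scale and shares on the linear scale, by an exact two-sided permutation test over the 6 assignments. Width in shared regions is the log2 ratio of mean called bases.

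Genes were named by a rule set in advance: Mettl14 and Mettl3, the 10 knockout-only and 10 control-only genes of each mark with the largest smaller width of the calling lists, the 10 genes co-marked in the knockout alone with the widest H3K4me3 peaks by the same ranking, and up to 4 members per class of each gene list in list order. Predicted genes and clones were not named, and the results of some list members are not reported here. The 14 gene lists were naive and core pluripotency, formative and primed pluripotency, Hox clusters, ectoderm and neural lineage, mesoderm lineage, endoderm lineage, developmental ligands, m6A machinery, Polycomb and H3K27 demethylases, H3K4 methylases and demethylases, housekeeping, germline, imprinted and 2-cell-like genes. The 3 cell type lists were fibroblast (feeder), trophectoderm and primitive endoderm markers. Of 355 listed genes 354 were found in the table, all but Dux. Some developmental genes such as Eomes stand in more than 1 list. Each list was tested by Fisher's exact test against other protein-coding genes called in neither list of the opposite condition, with Benjamini-Hochberg adjustment over 102 tests. Of these 11 had a raw p below 0.05 and 5 an adjusted p below 0.05. Genes, not libraries, are the units of these tests.

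The counting steps were tested on simulated data: of 100 genes planted per direction and mark among 21887 genes, 100 were recovered with 0 extra. Planted peaks touched the windows of genes with no deposited peak near them and no window shared with another gene. Full recovery thus checks the counting code, not unreplicated calls, unequal list lengths or shared windows. Of 1000 random lists of 20 genes, 2.7% gave a Fisher p below 0.05. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and Matplotlib 3.10.9.

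The alternatives set in advance were each library left out, the wider 50% of each list, lists of equal length per mark, windows of 500 bp and 2500 bp, a minimum overlap of 50%, peaks merged over gaps up to 1 kb, autosomes only, calls in at least 1 list, and a replicate block. Alternatives added after the data were seen were ranking by file order, the whole gene span as the window, and a test of lists among genes called in both lists of a condition. Unless file order is named, the wider 50% and equal length kept the widest peaks of each list, with ties in file order. Where minimum-width peaks exceed 50% of a list, its wider 50% still holds some of them. Leaving out a library took the list of its condition and number out of every mark, which matters where marks are combined.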

Results

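METTL14 is the partner of METTL3 in the enzyme complex that writes N6-methyladenosine (m6A) on RNA. The series examined how histone modifications change in mouse embryonic stem cells (mESCs) that lack it. The cells, of the C57BL/6 strain, were kept in serum medium with LIF and inhibitors of GSK3 and MEK, which hold mESCs in a naive, undifferentiated state. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done in Mettl14 control and Mettl14 knockout cells for 3 marks. H3K4me3 marks active and poised promoters, H3K27ac marks active promoters and enhancers, and H3K27me3 is laid down by Polycomb repressive complex PRC2. Each mark had 2 control and 2 knockout libraries, which gives 12 peak lists. The other 4 libraries were inputs, not analysed here. Read depth and spike-in factors were not used here, so the depth behind each list is unknown and no counting interval is given for it. The labels give replicate numbers and nothing on separate cultures, so permutation p-values measure the spread between these samples, which may be technical. Fisher p-values take genes as units and do not measure that spread. With 2 lists against 2, the exact permutation test, two-sided throughout, cannot give a p below 0.333.

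A gene was read as called when a peak touched the window of 1 kb either side of either end of its annotated span, named a gene-end window here. The gene table carries no strand, so the start of transcription could not be told from its end. Calls of a gene in different lists need not overlap each other. "Knockout-only" below means called in both knockout lists and in neither control list of a mark, and "control-only" means the reverse.

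Mettl14 itself (mm10 chromosome 3, 123368295 to 123385990) had no H3K4me3 peak at its ends in either control list. The knockout lists held peaks of 1074 bp and 1295 bp across its higher-coordinate end. An H3K27ac peak lay at the same end in control replicate 1 (501 bp) and in both knockout lists (629 bp and 627 bp), and control replicate 2 had none. No H3K27me3 peak was called at either end in any list. Mettl3 (chromosome 14, 52294841 to 52308741) had no peak of any mark at its ends in any of the 12 lists. Peaks at gene ends cannot show whether coding sequence was deleted, so they do not check the knockout label.

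The H3K4me3 lists of the knockout cells were longer, wider and more often at gene ends. They held 8093 ± 53.7 peaks (SD, n = 2) against 2645 ± 303 in control cells (SD, n = 2), a 3.06-fold difference. They covered 8.01 ± 0.173 Mb against 1.67 ± 0.152 Mb, a 4.79-fold difference. At gene ends lay 71.8 ± 0.556% of knockout peaks and 56.9 ± 6.19% of control peaks, where randomly placed peaks gave 4.13% to 4.71%. In each of these measures both knockout lists lay above both control lists, by more than the spread between replicates (exact permutation p = 0.333, the smallest possible). The 649 regions called in all 4 lists were 2.04-fold wider in the knockout (median log2 ratio 1.03), and 99.4% of them were wider there. Their median width was 768 bp and 766 bp in the control lists and 1664 bp and 1613 bp in the knockout lists. With all 4 lists cut to the widest peaks at the length of the shortest, the log2 difference in covered length was 1.36, against 2.26 as deposited. The difference in share at gene ends, 14.9 percentage points as deposited, was 27.3 points at that length and 5.66 points in the wider 50% of each list. The equal-length cut compares the widest knockout peaks with most of the control peaks. A larger covered length in the knockout is thus largely built into it, and its share at gene ends is also selected on width.

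**Figure D1:**
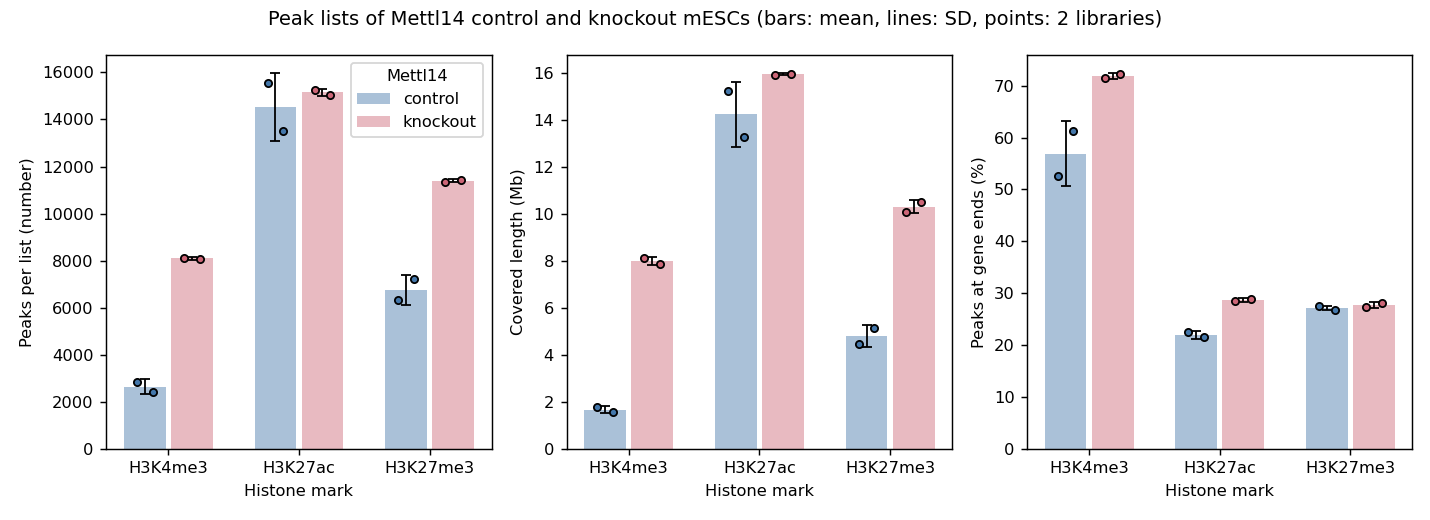
Peak number per list, covered length (Mb) and share of peaks at gene ends (%) for each mark; bars are means of 2 libraries, lines the SD, points single libraries, blue control and red knockout. The knockout to control distance in peak number is widest for H3K4me3 (8093 against 2645) and narrowest for H3K27ac (15164.5 against 14530.5).

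At the level of genes, 2959 of 21887 protein-coding genes were knockout-only for H3K4me3 and 6 were control-only. Pairing 1 control list with 1 knockout list gave 85 to 96 genes that were called in that pair alone. Ranked by the smaller of a gene's widths in the calling lists, as in all rankings below, the first knockout-only gene was Nsd1, an H3K36 methyltransferase (chromosome 13, 55209782 to 55318325), with widths of 3413 bp and 3370 bp. Nanog, a core transcription factor of naive pluripotency (chromosome 6, 122707489 to 122714633), had peaks of 3162 bp and 3981 bp over its lower-coordinate end and no peak in either control list. Jarid2, a PRC2 cofactor (chromosome 13, 44730774 to 44921643), had 3001 bp and 4121 bp. Smad7, an inhibitor of TGF-beta signalling (chromosome 18, 75367365 to 75395935), had 2995 bp and 3243 bp. The other genes among the top 10 were Ankrd17, Rdh10 (a retinol dehydrogenase), Kmt2e, Sp3 (a GC-box transcription factor), Zfp827 and Pcbp1, with smaller widths of 2626 bp to 3033 bp. The 6 control-only genes were Atg3, Slc35a5, Crem, Oxr1, Rbm28 and Tnrc18. Atg3 and Slc35a5 lie side by side on chromosome 16 and share their peak, and the control-only peaks were 501 bp to 864 bp wide.

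These counts depend on list length. With every H3K4me3 list set to the length of the shortest, 637 genes were knockout-only and 70 control-only. Leaving out 1 list at a time gave 3774 to 4285 knockout-only and 20 to 100 control-only genes. With fewer lists fewer calls, or fewer absences of a call, are required.

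Genes of the naive and core pluripotency list carried H3K4me3 in both knockout lists at 16 of 25 members and in both control lists at 5. Sox2, Klf2, Klf4 and Tdgf1 were among the 5 called in all 4 lists. At Sox2 the widths were 501 bp and 501 bp in the control lists and 3501 bp and 2829 bp in the knockout lists. At Klf4 they were 501 bp and 501 bp against 3431 bp and 4424 bp. The 4 knockout-only members were Nanog, Zfp42 (Rex1, a marker of naive cells), Sall4 and Nr0b1. Pou5f1 (Oct4), picked after its values were seen, had a peak of 1266 bp in control replicate 1, none in control replicate 2, and 2618 bp and 2825 bp in the knockout lists. The 4 knockout-only members were 33.3% of the 12 that no control list called, against 15.5% of other genes (Fisher's exact test, adjusted p = 0.696). Among genes called in both knockout lists the direction was the opposite. There 25.0% of this list (4 of 16) and 56.5% of other genes were knockout-only (Fisher's exact test, adjusted p = 0.222), a comparison added after the data were seen.

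The m6A machinery, H3K4 enzyme and Polycomb lists passed the test for knockout-only H3K4me3. Of the m6A machinery, 11 of the 14 members called in neither control list were knockout-only, 78.6% against 15.5% of other genes (odds ratio 19.99, Fisher's exact test, adjusted p = 2.96e-05). Mettl14, Wtap, Virma and Rbm15, all parts of the writer complex, were among the 11, while Mettl3 and the demethylase Fto had no call in any list. Of the H3K4 methylases and demethylases, 7 of 11 were knockout-only (63.6%, odds ratio 9.53, Fisher's exact test, adjusted p = 0.0103), among them the methyltransferases Kmt2a, Kmt2b, Kmt2c and Kmt2d. Of the Polycomb and H3K27 demethylase genes, 10 of 21 were knockout-only (47.6%, odds ratio 4.95, Fisher's exact test, adjusted p = 0.0112), among them Ezh1, Jarid2 and Cbx2. Of the housekeeping genes, 4 of 8 were knockout-only and the list did not pass (Fisher's exact test, adjusted p = 0.224), namely Actb, Tbp, Pgk1 and Psmb2. Counted over all 20 housekeeping genes, 9 were called in both control lists and 16 in both knockout lists.

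The members of these lists were not shown to stand apart from other genes that carried H3K4me3 in the knockout. Among genes called in both knockout lists, 64.7% of m6A machinery genes (11 of 17) were knockout-only, against 56.4% of other genes (Fisher's exact test, adjusted p = 1.0). The values were 52.6% (10 of 19) for the Polycomb list and 53.8% (7 of 13) for the H3K4 enzymes, both with adjusted p = 1.0 by Fisher's exact test. For the housekeeping genes the share was 25.0% (4 of 16) against 56.5% of other genes (Fisher's exact test, adjusted p = 0.222). This comparison was added after the data were seen. At equal list length 0 lists passed, in the wider 50% of each list the m6A machinery alone, and the H3K4 enzyme list also failed with windows of 500 bp (Fisher's exact test, adjusted p = 0.138) and 2500 bp (adjusted p = 0.693).

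Developmental genes held few H3K4me3 calls. Of 39 Hox genes, 0 were called in both control lists and 4 in both knockout lists, and Hoxa5, Hoxa6 and Hoxc13 were knockout-only. The neighbours Hoxa5 and Hoxa6 share 1 peak per knockout list. The mesoderm list had 3 knockout-only members, Eomes, Isl1 and Twist1, and the developmental ligands had 1, Bmp7. Of the formative and primed pluripotency genes Zic2, Etv4 and Tcf15 were knockout-only. In the endoderm list Foxa3 was called in all 4 lists and no member was knockout-only. Neither these lists nor the ectoderm and neural list passed the test (Fisher's exact test, adjusted p above the threshold of 0.05).

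**Figure D2:**
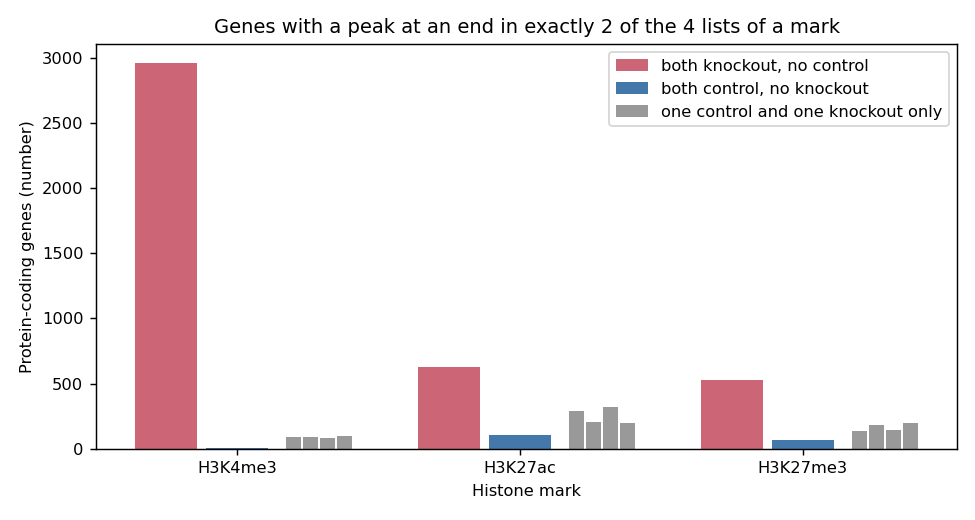
Number of protein-coding genes with a peak at an end in exactly 2 of the 4 lists of a mark; red bars count both knockout lists, blue bars both control lists, grey bars the 4 pairs of 1 control and 1 knockout list. For H3K4me3 the bars stand at 2959 (knockout), 6 (control) and 85 to 96 (pairs).

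H3K27ac differed less between the conditions. The lists held 15164.5 ± 150.6 peaks in knockout and 14530.5 ± 1429 in control cells (SD, n = 2 each; 1.04-fold, exact permutation p = 1.0), a difference within the spread between the control replicates. Covered length was 16.0 ± 0.0446 Mb against 14.3 ± 1.38 Mb (1.12-fold). The share of peaks at gene ends was higher in both knockout lists, 28.7 ± 0.341% against 22.0 ± 0.688%, a difference of 6.74 percentage points (exact permutation p = 0.333, the smallest possible). Genes with a call numbered 4826.5 ± 9.19 in knockout and 3480.5 ± 450.4 in control lists. The 2913 regions called in all 4 lists were 1.101-fold wider in the knockout (median log2 ratio 0.14), and 61.3% of them were wider there.

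For H3K27ac 630 genes were knockout-only and 108 control-only, while pairs of 1 control and 1 knockout list gave 200 to 320. Over regions, 1297 were knockout-only and 817 control-only, and the pairs gave 751 to 961. Leaving out a control list turned this order. Without control replicate 1 there were 2397 knockout-only and 6611 control-only regions, and without control replicate 2 there were 2089 and 7896. With 1 control list left, 1 call makes a region control-only, so unreplicated control peaks count, while knockout-only regions still need 2 calls. The turn is thus favoured by construction and says little on how steady the order is. By smaller width, the first knockout-only genes were Ctbp2, a transcriptional corepressor (chromosome 7, 132986998 to 133124009; 3813 bp and 3289 bp), and Dyrk1a, a kinase gene (chromosome 16, 94569947 to 94695519; 3474 bp and 2973 bp). Tceanc2 and Tmem59 followed, sharing 1 peak on chromosome 4 (2669 bp and 3559 bp). The others of the top 10 were Msln, Morf4l2, Txnl4a, Msl1, Sqstm1 (an autophagy receptor) and Mcm4 (a subunit of the replicative helicase), with smaller widths of 1793 bp to 2597 bp. By smaller width, the first control-only genes were Zfp958 (2987 bp and 1091 bp), the purine synthesis genes Paics and Ppat with a shared peak (1072 bp and 1100 bp) and Nfib (chromosome 4, 82290173 to 82506751; 1287 bp and 1012 bp). Fastkd3 and Mtrr with a shared peak, Elf3, Pml, Zbtb8a and Fbxo27 completed the 10. The widest Elf3 peaks of the control replicates did not overlap each other. Leaving out 1 list at a time moved the gene counts to 1023 to 1636 knockout-only and 289 to 689 control-only.

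H3K27ac was present at pluripotency genes in both conditions. Of the 25 naive and core genes, 12 were called in both control lists and 14 in both knockout lists, and 11 of them in all 4, Pou5f1, Nanog, Sox2 and Klf2 among them. At Nanog the widths were 8081 bp and 6431 bp in control and 8423 bp and 8321 bp in knockout lists. At Pou5f1 they were 6368 bp and 5999 bp against 5938 bp and 9027 bp. Zfp42 was knockout-only (3658 bp and 1208 bp), and Lefty2, an inhibitor of Nodal signalling, was control-only (501 bp and 501 bp). H3K27ac was called in all 4 lists at 10 of 20 m6A machinery genes (Wtap, Rbm15, Rbm15b and Ythdf1 among them) and at 10 of 20 housekeeping genes. The same class held 9 of 31 Polycomb list genes (Ezh2, Eed, Suz12 and Rbbp7 among them) and 6 of 17 H3K4 enzymes (Kmt2b, Setd1a, Wdr5 and Kdm5a among them). Knockout-only members were Igf2bp2 in the m6A list, Rbbp4 in the Polycomb list, Psmb2 among housekeeping genes, Bmp7 among ligands and Hoxc13 among Hox genes. Of the formative, ectoderm, mesoderm and endoderm genes 0 were called in both lists of either condition. With Fisher's exact test, 0 of the H3K27ac lists passed after adjustment over all 102 tests of the 3 marks.

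The antibody label of the H3K27ac libraries names the H3K4me3 antibody, so the lists of these marks were set against each other. H3K27ac peaks overlapped an H3K4me3 peak of the same condition at 7.497 ± 0.265% in control and 23.5 ± 0.447% in knockout lists. The reverse shares were 41.7 ± 2.18% and 43.9 ± 0.807%. At Nanog both control lists held wide H3K27ac peaks and no H3K4me3 peak. With lists of a mark at equal length, the difference in the first share was 5.58 percentage points, against 15.95 with the lists as deposited. At gene ends lay 22.0% (control) and 28.7% (knockout) of H3K27ac peaks, against 56.9% and 71.8% of H3K4me3 peaks. The widest peak of each list was 20743 bp to 21562 bp for H3K27ac and 3073 bp to 5836 bp for H3K4me3. These values argue against the H3K27ac lists being further H3K4me3 lists. They cannot show which antibody was used.

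H3K27me3 was more widely called in the knockout. The lists held 11397.5 ± 68.6 peaks against 6757.5 ± 630.0 in control cells (SD, n = 2 each; 1.69-fold) and covered 10.3 ± 0.280 Mb against 4.80 ± 0.469 Mb (2.15-fold). Both knockout lists lay above both control lists by more than the spread between replicates (exact permutation p = 0.333, the smallest possible). The share at gene ends was 27.7 ± 0.535% and 27.1 ± 0.417%, a difference of 0.531 percentage points and within that spread (exact permutation p = 0.667). It depends on the setting: the difference was -2.76 points with a window of 2500 bp and 1.79 points at 500 bp. It was 1.86 points in the wider 50% of each list and 10.9 points at equal list length. In each of these settings the lists of the conditions lay apart (exact permutation p = 0.333). The equal-length cut sets the widest knockout peaks against most of the control peaks, so its value is selected on width. The 881 regions called in all 4 lists were 1.82-fold wider in the knockout (median log2 ratio 0.86), with medians of 2052 bp and 2132 bp against 1002 bp and 1015 bp, and 86.7% of them were wider there.

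For H3K27me3 531 genes were knockout-only and 69 control-only, and pairs of 1 control and 1 knockout list gave 135 to 195. By smaller width, the first knockout-only genes were Egr3, an immediate early transcription factor (chromosome 14, 70077317 to 70082613; 8594 bp and 5798 bp), and Fgfr3, a fibroblast growth factor receptor (chromosome 5, 33721724 to 33737068; 5734 bp and 8023 bp). Ovol1 and Ap5b1 shared a peak on chromosome 19 (5241 bp and 5227 bp). Nptx1, the neighbours Pygm and Rasgrp2, Efna3, Slc35d3 and Adamtsl5 completed the top 10, with smaller widths of 3657 bp to 4799 bp. Among the control-only genes, T (Brachyury), which drives mesoderm formation (chromosome 17, 8434423 to 8442496), had peaks of 1210 bp and 923 bp in the control lists and none in the knockout lists. Wnt5b (chromosome 6, 119432531 to 119544824) had 935 bp and 2773 bp, and Lgr5, a Wnt target and stem cell receptor (chromosome 10, 115450314 to 115587780), had 1196 bp and 874 bp. At both Wnt5b and Lgr5 these peaks of the control replicates lay near the same gene end and did not overlap each other. The other control-only genes of the top 10 were Tmod1 (2440 bp and 1595 bp), Tmem114, Tdrd5, Hs3st6, Foxd1, Cdh8 and Car4. Leaving out 1 list at a time gave 856 to 1195 knockout-only and 170 to 320 control-only genes.

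Polycomb target families carried H3K27me3 in both conditions. Of 39 Hox genes, 19 were called in both control lists, 32 in both knockout lists and 15 in all 4, among them Hoxa7, Hoxa9, Hoxa13 and Hoxb3. No Hox gene lacked a call in every list. Over the Hoxa cluster (chromosome 6, 52155367 to 52260880), peaks covered 12.4% and 20.7% of the sequence in control lists and 38.8% and 33.5% in knockout lists. The means were 11.04 ± 2.43% and 24.0 ± 4.20% over Hoxb, 14.4 ± 6.04% and 24.0 ± 0.536% over Hoxc, and 14.7 ± 4.03% and 26.1 ± 0.0635% over Hoxd (SD, n = 2 each; exact permutation p = 0.333 in each cluster, the smallest possible). Hoxa3, Hoxb4 and Hoxc13 were knockout-only, which is 3 of the 3 Hox genes that no control list called (Fisher's exact test, adjusted p = 0.00106). Hoxb2 and Hoxc12 were control-only, 2 of the 4 that no knockout list called (odds ratio 267.1, Fisher's exact test, adjusted p = 0.00295). Both results rest on few genes, and neighbouring genes in a cluster can share peaks. Hoxa3 was not free of the mark in control cells. Both control lists held H3K27me3 peaks within its span (52169059 to 52213067) but outside its gene-end windows. Examples are 52170097 to 52170597 in control replicate 1, just past the window, and 52173372 to 52174655 in control replicate 2. With a window of 500 bp neither passed, with 2500 bp no Hox gene was left to test, and in the wider 50% of each list the control-only result was lost (adjusted p = 1.0, Fisher's exact test). Among genes called in both knockout lists, 9.38% of the Hox genes (3 of 32) and 31.3% of other genes were knockout-only (Fisher's exact test, adjusted p = 0.172).

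**Figure D3:**
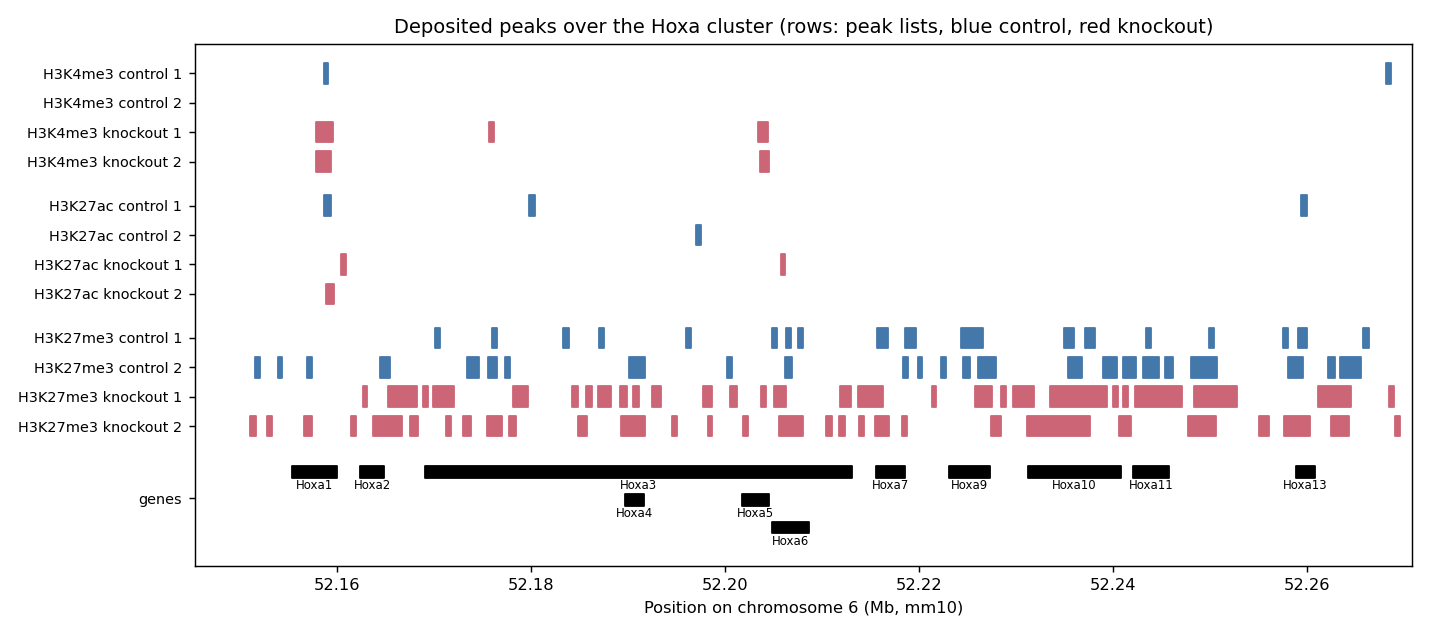
Map of the Hoxa cluster with the deposited peaks of all 12 lists (1 row per list; blue control, red knockout; x axis, position on chromosome 6 in Mb, mm10) above the Hox genes (black). H3K27me3 peaks cover 12.4% and 20.7% of the cluster in the control rows and 38.8% and 33.5% in the knockout rows.

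Other developmental lists held the mark at many of their members. H3K27me3 was called in both lists at 14 (control) and 18 (knockout) of 25 ectoderm and neural genes, with Pax2, Neurog2, Nkx2-2 and Nkx6-1 among the 10 called in all 4. Pax6, the master regulator of eye development, was control-only (501 bp and 501 bp). The counts were 10 and 13 of 25 for mesoderm genes, with Eomes, Mesp1, Tbx5 and Evx1 among the 6 called in all 4, and Meox1 (1697 bp and 1146 bp) was among the knockout-only genes. They were 5 and 7 of 20 for endoderm genes, where the peaks at Foxa2 were 501 bp and 1102 bp wide in control and 4023 bp and 5018 bp in knockout lists. They were 11 and 13 of 25 for developmental ligands, with Wnt1, Wnt3a, Wnt5a and Wnt7b among the 9 called in all 4. Of the formative and primed genes 3 and 6 of 15 were called, and Fgf5 and Zic2 were knockout-only. The widest Zic2 peak lay at the higher-coordinate end in knockout replicate 1 and at the lower-coordinate end in knockout replicate 2. None of these lists passed after adjustment (Fisher's exact test; mesoderm knockout-only adjusted p = 0.112, formative knockout-only adjusted p = 0.194, ectoderm control-only adjusted p = 0.112). The mesoderm knockout-only result did pass in the wider 50% of each list (3 of 9, adjusted p = 0.02499) and at equal list length (3 of 6, adjusted p = 0.00538), both by Fisher's exact test. Both rest on the few mesoderm genes that no control list called. Among genes called in both deposited knockout lists, 15.4% of mesoderm genes (2 of 13) and 31.0% of other genes were knockout-only. Of the naive and core pluripotency genes 0 and 2 of 25 were called, and Esrrb was knockout-only (767 bp and 501 bp). The Polycomb list had 0 and 3 of 31, with Cbx2 knockout-only. The m6A machinery, H3K4 enzyme and housekeeping lists had 0 calls in any list.

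**Figure D4:**
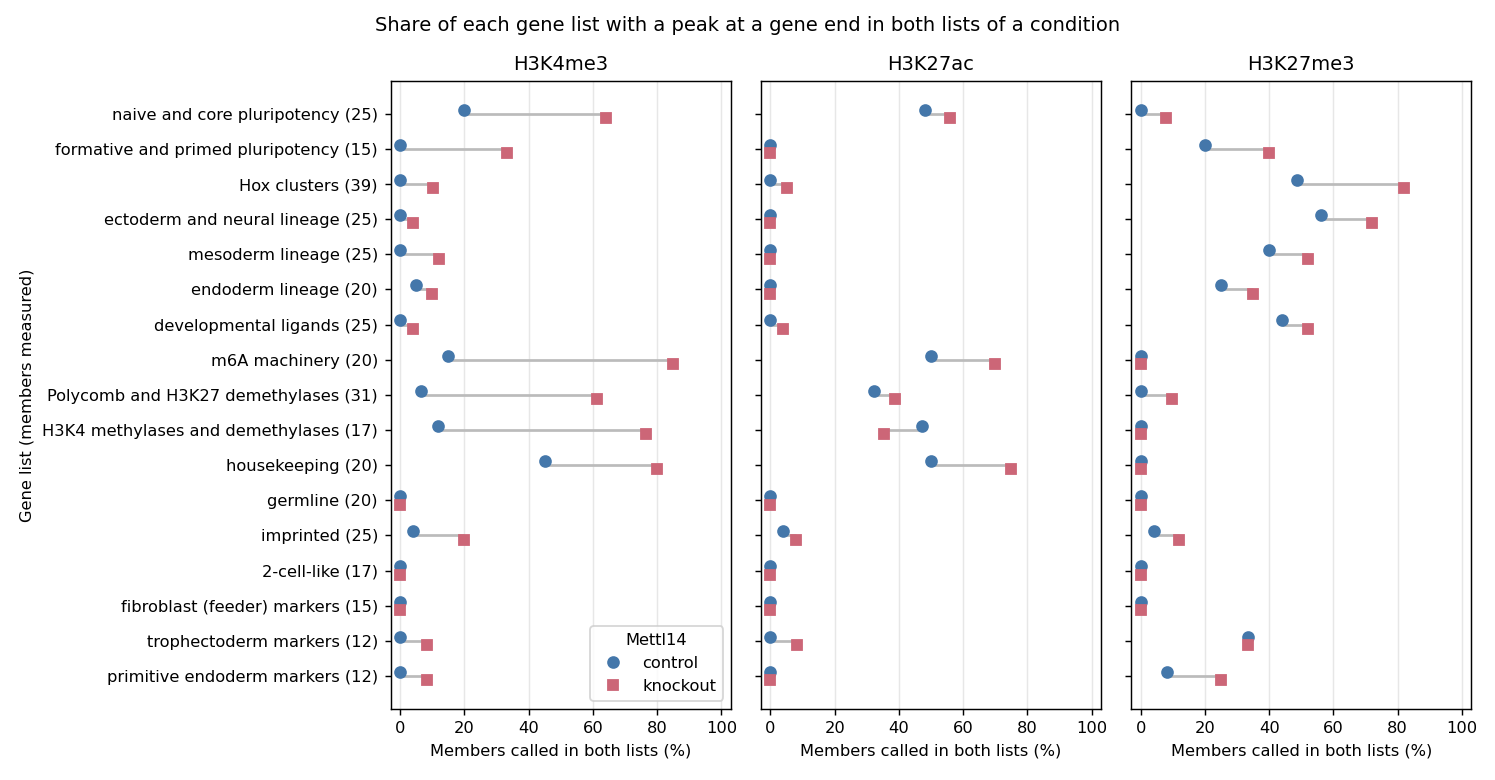
Share of each gene list (%, x axis; list size in parentheses) with a peak at a gene end in both control lists (blue circles) and both knockout lists (red squares), 1 panel per mark. For H3K4me3 the m6A machinery stands at 3 of 20 genes in control and 17 of 20 in knockout lists, and for H3K27me3 the Hox genes stand at 19 and 32 of 39.

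Promoters that carry both H3K4me3 and H3K27me3, a state typical of developmental genes in mESCs, were sought as genes called for both marks in both lists of a condition. There were 0 such genes in control and 148 in knockout cells, where independent placement of the calls gave 24.3 and 411.2. Single pairs of lists gave 27 to 52 co-marked genes in control and 476 to 564 in knockout cells. Of the 148, H3K27me3 was present in both control lists at 24 genes, in 1 at 62 and in neither at 62. H3K4me3 was present in both control lists at 2, in 1 at 20 and in neither at 126. The first by smaller H3K4me3 width were Kdm2a, an H3K36 demethylase (chromosome 19, 4316144 to 4398721; H3K4me3 widths 3134 bp and 2601 bp, H3K27me3 widths 633 bp and 660 bp), Ccdc106, Zic2 (chromosome 14, 122475384 to 122480328), L3mbtl3 and Mllt3. Mtcl1, Plcxd1, Lor, Riox1 and Syne2 completed the top 10. Co-marking of a gene is often not co-marking of a site. The marks lay at the same gene end in both knockout replicates at 114 of the 148 genes, in 1 at 17 and in neither at 17. Their peaks overlapped in both replicates at 59 genes, in 1 at 48 and in neither at 41, among the last Ccdc106, L3mbtl3, Mtcl1 and Plcxd1. Members of the lists included Zic2, Hoxa5, Hoxa6, Hoxc13, Eomes, Cbx2 and Foxq1, of which Hoxa5 and Hoxa6 share their H3K4me3 peak. With lists of each mark at equal length the numbers were 0 and 13, and with calls in at least 1 list per mark they were 116 and 1074.

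Over all genes, knockout-only H3K4me3 fell less often on genes that carried H3K27me3 in control cells. The test took genes not called for H3K4me3 in both control lists. Of the 792 with H3K27me3 in both control lists, 42 were knockout-only for H3K4me3 (5.30%). Of the other 20424 genes, 2917 were (14.3%; odds ratio 0.336, confidence interval 0.246 to 0.460, Fisher's exact test, p = 2.10e-15). Genes were the units of this test, so it describes these lists, and its interval does not hold the spread between libraries. The same-numbered lists of both marks in 1 condition were then left out together. This gave log2 odds ratios of -1.86 to -0.70, against -1.57 with all lists. Among genes called for H3K4me3 in both knockout lists the direction was the opposite: 42 of 43 genes with H3K27me3 in both control lists were knockout-only (97.7%). Of all 5242 genes called in both knockout lists, 2959 were knockout-only. Stratified by knockout peak width, the odds ratio against genes without H3K27me3 in both control lists was 13.81 (confidence interval 2.07 to 91.9). It rests on the 1 gene of the 43 that had a control call, in the class of narrowest knockout peaks. Peak by peak, 0.611 ± 0.0581% of H3K27me3 peaks overlapped an H3K4me3 peak in control and 3.73 ± 0.263% in knockout cells (SD, n = 2 each; exact permutation p = 0.333, the smallest possible).

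How far lists of a condition repeat each other bears on all these counts. For H3K4me3, 24.1% of the peaks of a control list were overlapped in the other control list and 57.9% in a knockout list. Of knockout peaks 62.7% were overlapped in the other knockout list and 18.6% in a control list. For H3K27ac the 4 shares lay between 35.5% and 41.6%. For H3K27me3, 21.6% of control peaks were overlapped in the other control list and 35.0% in a knockout list. Of knockout H3K27me3 peaks, 30.5% were overlapped in the other knockout list and 18.9% in a control list. Such shares depend on the length of the list searched, and the knockout lists of H3K4me3 and H3K27me3 were longer. At equal length by width the H3K4me3 shares, in the order above, were 26.0%, 42.3%, 68.7% and 41.5%. Those of H3K27me3 were 22.4%, 32.7%, 41.3% and 29.4%.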

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

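The alternatives that rank by file order, take the whole gene span or test lists among called genes were chosen after the data were seen. A count was taken as steady within 1.5 times its value, an untested value within 1 SD of the replicates (for overlaps the SD within conditions, set after the values were seen in place of one over both conditions), and a tested value if its direction held and its test (exact or permutation) stayed on the same side of p = 0.05. By these limits, 191 of 293 values under an alternative were steady, 92 moved and 10 turned direction. Of the 10, 4 arose without control replicate 1 and 5 without control replicate 2. All of these but the H3K27ac peak number were region counts, where needing a call in 1 control list alone favours the turn. With 2 lists against 2 no permutation p can pass 0.05, so a tested value can move far and still count as steady. Depth is unknown, so what it limits could not be set. No pairing of the samples by replicate number was detected: deviations of same-numbered libraries correlated at 0.00597, 0.0162 and 0.00110 across regions of H3K4me3, H3K27ac and H3K27me3. Many peaks are not repeated between lists of a condition, which could hide a pairing, so it is not excluded. With the replicate block the log2 difference in peak number was 1.62, 0.07 and 0.76 for these marks, as without it, and the smallest sign-flip p is 0.5. No direction changed, which arithmetic fixes for all measures but shared width, so the block tests little. Within replicate numbers 1 and 2 the H3K27ac log2 peak number differed by -0.025 and 0.155. The H3K27me3 share at gene ends differed by -0.14 and 1.20 points.

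H3K4me3 knockout-only and control-only regions numbered 1525 and 1 in the wider 50% of each list, 1680 and 2 in the first 50% by file order, 500 and 66 at equal length by width, and 643 and 73 at equal length by file order. For genes these were 1653 and 1, 1840 and 2, 637 and 70, and 786 and 75. Control-only genes numbered 17 at 50% overlap, 3 with a window of 500 bp and 22 with gene spans. H3K27ac regions numbered 629 and 405 (wider 50%) and 708 and 415 (file order), with 345 knockout-only genes (wider 50%), 71 control-only genes (file order) and 207 (gene spans). H3K27me3 regions numbered 748 and 133 (wider 50%), 758 and 131 (file order), and 671 and 685 knockout-only at equal length by width and by file order, with 45 control-only genes at 500 bp. Shorter lists hold fewer peaks to count. The share of H3K27me3 peaks at gene ends turned to -2.76 percentage points with a 2500 bp window, and the cause was not tested. It was 1.79 at 500 bp, 1.86 in the wider 50% and 10.9 at equal length. The H3K4me3 share difference was 5.66 points in the wider 50% and 27.3 at equal length. There the log2 difference in covered length was 1.36 for H3K4me3 and 0.76 for H3K27me3. Equal length by width keeps the widest knockout peaks and most control peaks, so these covered lengths cannot show a difference free of the cut. Overlap of lists within conditions minus between them was 5.21 points for H3K4me3 and 1.76 in the wider 50%, and for H3K27me3 it was -0.904 as reported and 0.788 at equal length, where its sign turned.

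For H3K4me3 1 gene list passed in the wider 50%, 2 at 500 bp, 2 at 2500 bp, 0 at equal length and 0 among genes called in both lists. For H3K27me3 the Hox and mesoderm lists passed in the wider 50% and at equal length, and 0 lists at 500 bp, 0 at 2500 bp and 0 among genes called in both lists. Co-marked genes in control and knockout numbered 6 and 331 at 2500 bp, 116 and 1074 with calls in at least 1 list, and 18 and 441 with gene spans. In the knockout they numbered 65 at 500 bp, 35 (wider 50%), 33 (first 50% by file order), 13 and 12 (equal length by width and by file order). The knockout minus control share of H3K27ac peaks on H3K4me3 was 17.99 points in the wider 50% and 5.58 at equal length.

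With 1 library left out, the numbers rise by construction: the reduced group needs a call in 1 list, so its unreplicated calls count, and calls of the other group need to be absent from 1 list. Ranges over the 4 libraries were 3628 to 5770 knockout-only and 15 to 1234 control-only H3K4me3 regions, 3774 to 4285 and 20 to 100 H3K4me3 genes, 2089 to 7797 and 1450 to 7896 H3K27ac regions, 1023 to 1636 and 289 to 689 H3K27ac genes, 1729 to 8022 and 497 to 3715 H3K27me3 regions, and 856 to 1195 and 170 to 320 H3K27me3 genes. Control-only regions exceeded knockout-only ones without control replicate 1 (H3K27ac 6611 against 2397, H3K27me3 3715 against 1729) and without control replicate 2 (7896 against 2089, 3057 against 1831). The H3K27ac log2 peak number turned to -0.035 without control replicate 2 (range -0.035 to 0.17). Co-marked genes ranged from 0 to 52 in control and 148 to 564 in knockout. For them and for the log2 odds ratio below, the same-numbered lists of both marks were left out together. The co-marked numbers of the reduced condition were 36 and 52 in control and 509 and 564 in knockout. They are those of single pairs of lists and give no separate check. H3K4me3 peak number (1.501 to 1.74), covered length (2.17 to 2.36), share at gene ends (10.5 to 19.3 points) and shared width (0.98 to 1.05) kept their direction. So did H3K27me3 peak number (0.66 to 0.85), covered length (1.01 to 1.21) and shared width (0.72 to 0.84), the H3K27ac share at gene ends (6.26 to 7.23 points), and the log2 odds ratio of H3K27me3 genes (-1.86 to -0.70).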

Other observations

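The test on housekeeping genes below was chosen only after its result was seen, and so was the comparison of lists among called genes. H3K27me3 peaks were scarce on the X chromosome, 0.556 ± 0.0204% of control and 0.680 ± 0.0393% of knockout peaks (SD, n = 2 each), while H3K4me3 had 2.63% in both conditions. No peak was called on the Y chromosome. The 2-cell-like genes, such as Zscan4a and Zscan4b, had 0 calls for any mark in any list. Of 20 germline genes 0 were called in both lists of any condition. Of 25 imprinted genes, Ube3a carried H3K4me3 and H3K27ac in all 4 lists and Cdkn1c carried H3K27me3 in all 4. Kcnq1ot1 and Plagl1 were knockout-only for H3K4me3 and Nnat for H3K27me3.

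Markers of other cell types were rarely called for the active marks. Of 15 fibroblast (feeder) markers 0 were called in both lists of a condition for any mark. Of 12 trophectoderm markers, Eomes was knockout-only for H3K4me3 and Gata3 for H3K27ac and H3K27me3, Krt7 was control-only for H3K27me3, and Cdx2, Eomes and Ascl2 carried H3K27me3 in all 4 lists. Of 12 primitive endoderm markers Foxq1 was knockout-only for H3K4me3 and carried H3K27me3 in all 4 lists. None of these lists passed Fisher's exact test after adjustment. Eomes also stands in the mesoderm list, and Gata4, Gata6, Sox17, Sox7, Afp, Ttr and Dab2 stand in the endoderm list as well.

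For the first pattern, the larger number of H3K4me3 calls in the knockout, a candidate explanation is lower call sensitivity in the control lists: 45.0% of 20 housekeeping genes were called in both control lists (exact 95% interval 23.1% to 68.5%) against 80.0% in both knockout lists, and Actb had no control call. Among genes called in both knockout lists, those called in both control lists rose from 0.571% in the narrowest of 10 classes by knockout width to 39.2% in the widest. A further hypothesis, a gain directed to genes with H3K27me3 in control cells, had an odds ratio of 13.81 stratified by knockout width (95% interval 2.07 to 91.9), since 42 of 43 such genes (97.7%) had no control call. It rests on 1 gene with a call and can concern at most those 43 genes, and over all genes knockout-only H3K4me3 was rarer at H3K27me3 genes (odds ratio 0.336). A global rise of H3K4me3 in the knockout, which the design names, stays open and was not tested, since a rise in every housekeeping gene would look the same in these lists.

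The second pattern is the 148 co-marked genes in the knockout against 0 in control cells. At equal length the knockout number was 13 (exact Poisson 95% interval 6.92 to 22.2) against 0 (0 to 3.69), which decides little, since the control number was 0 before any cut and neighbouring genes can share peaks. Over single pairs of lists, 476 to 564 in knockout against 27 to 52 in control cells became 54 to 61 (mean 56.5) against 22 to 48 (mean 34.25) at equal length by width, and 38 to 48 against 22 to 48 by file order, so whether list length is the whole cause cannot be told. Less repeatable control lists may still contribute, since at equal length 26.0% of H3K4me3 control peaks and 68.7% of knockout peaks were overlapped in the other list of their condition (22.4% and 41.3% for H3K27me3), as may an effect of the knockout, and neither was tested. The 148 stayed below the 411.2 that independent placement of the same calls gives, and the single knockout pairs below their own 857 to 882.

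The last pattern is the higher share of H3K27ac peaks at gene ends in the knockout. More unreplicated calls in the control lists do not explain it: among peaks overlapped in the other list of their condition the difference was 9.21 percentage points (8.76 to 9.66 over pairs of lists), against 6.74 over all peaks. Whether new H3K27ac calls gather where H3K4me3 was newly called cannot be told. Among 2282 genes with H3K4me3 in both knockout lists and H3K27ac in neither control list, 16.3% of those without control H3K4me3 calls and 22.9% of the others were knockout-only for H3K27ac (odds ratio 0.656, 95% interval 0.518 to 0.831), but within 10 classes by knockout H3K4me3 width the odds ratio was 0.929 (0.721 to 1.198), an interval that includes 1. A difference in precipitation between the conditions and an effect of the knockout both stay open and untested.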
